A study of Mus musculus with 22 samples.

How the data were processed

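Gene expression was measured on two-colour spotted arrays in hepatocellular carcinomas of Mdr2-knockout mice, in carcinomas of Mdr2-knockout mice that also carried the IkB super-repressor (IkB-SR) in hepatocytes, and in wild-type liver of the same genetic background. Per the labels, RNA was amplified with a T7 primer and each sample was hybridised on 2 arrays, with the dyes swapped, against a universal mouse reference RNA. The 22 arrays therefore held 11 RNA samples: 4 Mdr2-KO tumours (replicates 1, 2, 5 and 7), 6 IkB-SR tumours (replicates 3, 4, 6, 8, 9 and 10) and 1 wild-type liver. The labels give the sex of the mice as unknown. They also name mouse skin in the extraction protocol and a carcinoma stage for the wild-type liver. Neither was used.

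The deposited table holds 1 value per spot and array for 37632 spots, and was read as log2 ratios of sample over reference that the authors had already normalized. The log base is not stated in the labels. Base 2 was assumed, because the highest value of 8.35 would be a ratio of 325 on that scale and of 4212 with natural logs. Image analysis, background correction, normalization and spot filtering are not given in the sources used here. Array medians lay between -0.31 and 0.01. Between 19576 and 25000 spots per array carried a value, 16135 spots carried one on all 22 arrays and 10562 on none. Spot intensities were not analysed here, so the precision of single spots was judged only from the dye swap and from the number of samples.

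The dye-swapped arrays of each sample correlated positively across spots (Pearson's r from 0.861 to 0.988), so both orientations were already turned the same way. Sample over reference is the likely direction: the hepatocyte list averaged 4.87 in the wild-type liver. The spread of the dye difference split the samples at an SD of 0.5, a limit set after the values were seen. Mdr2-KO tumours 1 and 2 and IkB-SR tumours 3, 4, 9 and 10 formed dye batch 1 (SD 0.215 to 0.305). Mdr2-KO tumours 5 and 7, IkB-SR tumours 6 and 8 and the wild-type liver formed dye batch 2 (SD 0.662 to 0.758). Correlations of the dye difference between samples were 0.274 to 0.598 within batch 1, 0.779 to 0.933 within batch 2 and -0.235 to 0.325 between them.

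Platform annotation gave 1 gene symbol for 20879 spots, none for 16753 and several for 0. Of the symbols, 15688 were current in the mouse RefSeq gene table of assembly GRCm38.p6, 5005 were updated through synonyms and 186 were kept as given. Probes with the same symbol were averaged. A feature was tested when both arrays had a value in at least 3 Mdr2-KO and 4 IkB-SR tumours, which left 18190 of 23976 features (11880 named and 6310 unnamed), and 17419 against the wild-type liver.

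The arrays of a sample were averaged and 1 model with 3 group means was fitted to all 11 samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. The single wild-type liver was assumed to vary like the tumours. The gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation (14728 features with values in all samples), camera on ranks and fry. Single values and list means were compared between the 4 and 6 tumours by two-sided exact permutation over 210 splits, for which the smallest possible p is 0.00476. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. The groups, tests, 35 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested, which were 32. The erythroid, exocrine pancreas and Y chromosome lists had fewer.

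For the tumour comparison the rule named the 12 genes with the largest log2 difference in each direction among those past the threshold. Where fewer passed, it took up to 12 by smallest unadjusted p among genes with p under 0.05 and an absolute log2 difference of at least 1. Against the wild-type liver it named up to 10 genes per direction past the threshold in both tumour groups. The 3 members with the smallest p were named in each described list, and Abcb4, Nfkbia, S100a8, S100a9, Xist, Ddx3y and Eif2s3y always. S100a8 and S100a9 were included because a paper on this model is known to discuss them, so their choice was not blind to published results. Other genes named were chosen after their values were seen. Xist and Ddx3y had no named, measured feature.

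The procedure was tested on simulated data with 14728 features, 200 of them changed, in 5 simulations. For IkB-SR against Mdr2-KO tumours it recovered 76.2% of 2-fold and 95.4% of 4-fold changes, with 5.51% of calls false. For Mdr2-KO tumours against wild-type liver it recovered 47.0% and 81.6%, with 4.17% false. In each simulated comparison all 10 lists shifted by 0.6 were found and 0 of 140 unshifted lists were called. Genes were simulated independently of each other, so the list counts do not cover correlated genes. The noise was normal, without dye batch or sex, and the liver varied like the tumours. The recovery and false call rates hold for those settings and may not carry over to the real comparisons.

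Alternatives were centring each array, quantile normalization, single dye orientations, all arrays with a dye term, other filters on features, probes tested singly, robust eBayes, array weights, a fold threshold and leaving out each tumour. Dye batch as a block, the difference within each batch (1 fit with the spread pooled over both), the Eif2s3y log ratio as a covariate, the 7 tumours with low Eif2s3y, features measured in all 10 tumours, a threshold of 0.10 and exact permutation of list means were added after the data were seen.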

Results

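The series addressed which genes depend on NF-kB in liver tumours. Mice without Mdr2 (gene symbol Abcb4), the transporter that moves phospholipid into bile, develop hepatitis and then hepatocellular carcinoma. The IkB super-repressor is a form of the inhibitor IkB-alpha (Nfkbia) that holds NF-kB in the cytoplasm. Profiled were 4 carcinomas of Mdr2-KO mice and 6 carcinomas of Mdr2-KO mice with the repressor in hepatocytes, beside 1 wild-type liver. The sample labels number the tumours and do not say whether each came from a different mouse. All tests treated the tumours as independent. All values below are log2 ratios over the reference RNA, and differences between groups are log2 differences.

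Nfkbia, the parent gene of the transgene, averaged 0.13 ± 0.12 (SD, n = 4) in Mdr2-KO tumours and 1.95 ± 1.05 (SD, n = 6) in IkB-SR tumours, against 0.09 in the wild-type liver. It was higher by 1.82 (exact permutation p = 0.0429), and lay above all Mdr2-KO tumours in 5 of 6 IkB-SR tumours. The sample labelled IkB-SR replicate 8 went against its label, with an Nfkbia value of 0.003, while the other IkB-SR tumours lay at 1.69 to 3.11. Without this sample the difference was 2.21 (exact p = 0.00794, the smallest possible there). The sample was singled out by this same gene, so that p adds no separate support. Within dye batch 1 the difference was 2.29 and within dye batch 2, which holds that sample, 0.80; with the batch as a block it was 1.65. The exact p rose to 0.0833 when Mdr2-KO tumour 2, 5 or 7 was left out. Whether the Nfkbia probe reads the transgene's transcript is not given in the sources used here.

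Abcb4, the disrupted gene, averaged 2.95 ± 0.55 (SD, n = 4) in Mdr2-KO and 2.83 ± 0.48 (SD, n = 6) in IkB-SR tumours (exact permutation p = 0.695). In the wild-type liver it had a value of 4.46 on the Cy5 array alone, where the tumours ranged from 1.94 to 3.43. The position of the probe relative to the disrupted part is not given in the sources used here, so these values check nothing about the knockout. Eif2s3y, a Y chromosome gene, was low in all 4 Mdr2-KO tumours (-3.91 ± 0.16, SD) and in IkB-SR tumours 3, 4 and 10 (-3.54, -2.98 and -3.06). It was high in IkB-SR tumours 6 and 9 and the sample labelled IkB-SR replicate 8 (2.34, 2.46 and 1.64) and in the wild-type liver (2.33). Within dye batch 2 both IkB-SR tumours were high and both Mdr2-KO tumours low. Differences between the tumour groups in that batch cannot be separated from sex. Tumours with high Eif2s3y were thus found in the IkB-SR group and not in the Mdr2-KO group (difference 3.38, exact permutation p = 0.0381; 0.0556 without IkB-SR tumour 3, 4 or 10 and 0.103 without IkB-SR tumour 6 or 9 or the sample labelled IkB-SR replicate 8).

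**Figure D1:**
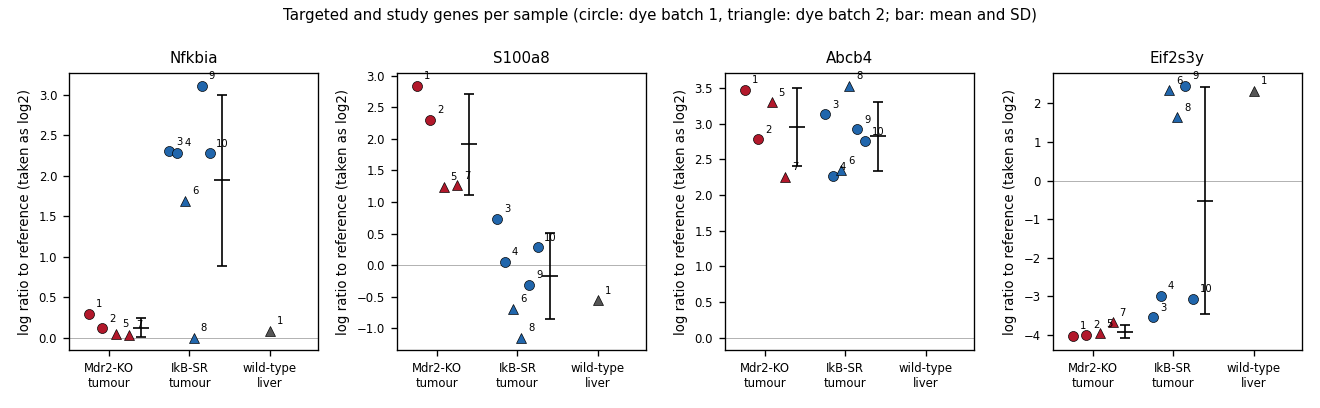
Log2 ratio over the reference RNA (vertical axes) of Nfkbia, S100a8, Abcb4 and Eif2s3y in each RNA sample by group, with circles for dye batch 1, triangles for dye batch 2 and bars for the mean and SD. Nfkbia lies at 0.04 to 0.30 in Mdr2-KO tumours and at 0.003 in the sample labelled IkB-SR replicate 8, and S100a8 lies lower in 6 of 6 IkB-SR tumours than in every Mdr2-KO tumour.

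S100a8, a calcium-binding protein of myeloid cells, was lower in all 6 IkB-SR tumours than in any Mdr2-KO tumour. It averaged 1.91 ± 0.79 (SD, n = 4) in Mdr2-KO and -0.18 ± 0.68 (SD, n = 6) in IkB-SR tumours, a difference of -2.09 or 4.26-fold (exact permutation p = 0.00476, the smallest possible). Over all features the adjusted p was 0.102, and 0.0247 with dye batch as a block; the difference was -2.38 in batch 1 and -2.17 in batch 2. S100a9, its partner in the calprotectin complex, gave a value on 8 of 8 Mdr2-KO arrays, 5 of 12 IkB-SR arrays and 1 of 2 wild-type arrays. Values on both arrays were present in 4 Mdr2-KO and 2 IkB-SR tumours (Fisher's exact p = 0.0762), too few for the filter. Both genes were chosen because a paper on this model is known to discuss them.

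Between IkB-SR and Mdr2-KO tumours no single feature passed the threshold; the leading lower genes included genes of liver macrophages and the leading higher ones Alb and Apoa2 of the hepatocyte list. The 12 leading lower genes lay below every Mdr2-KO tumour in 6 of 6 IkB-SR tumours. They were picked by the smallest p in this same comparison, so that separation adds no support. They included Kupffer cell genes: the phosphatidylserine receptor Timd4 (-1.11), Cd5l (-1.25), the ficolin Fcna (-1.62) and the folate receptor Folr2 (-1.61, 3.05-fold). The chemokines Ccl24 (-1.20), Cxcl9 (-1.64) and Pf4 (-1.32) were among them. So were the haem-degrading enzyme Hmox1 (-1.24), the water channel Aqp1 (-1.55), the transcription factor Maf (-1.09), the fatty acid binding protein Fabp7 (-1.06) and the matrix protein Emilin2 (-1.01). Their adjusted p-values in limma ran from 0.0522 for Ccl24 and Folr2 to 0.0588 for Cd5l, and their standard errors from 0.136 for Ccl24 to 0.242 for Fcna.

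Among the leading higher genes, Cat, the peroxisomal catalase, differed by 1.52 (SE 0.19, 2.86-fold, adjusted p = 0.0522 in limma), as the average of probes at 0.99 and 2.04. The others included the hepatocyte list genes Alb for albumin (1.17) and the apolipoprotein Apoa2 (1.18), and also the haem carrier Hpx (1.32), the apolipoprotein Apoe (1.25), the iron carrier Trf (1.19), the sterol carrier Scp2 (1.16) and Igfbp2 (1.02). The glutathione transferase Gstm3 (1.16), the transporter gene Slc35f2 (1.93) and the RNA gene Snhg11 (1.06) completed the 12 with Nfkbia (1.82, adjusted p = 0.178). Adjusted p-values of these others ran from 0.116 for Scp2 to 0.249 for Snhg11. Several were larger within dye batch 1 than within batch 2: Alb 1.55 and 0.45, Apoa2 1.68 and 0.23, Apoe 1.75 and 0.38, Gstm3 1.83 and 0.19, Trf 1.55 and 0.36. Cat was 1.72 and 1.19, Folr2 -1.37 and -1.99, Timd4 -1.20 and -1.10, and Cxcl9 -2.04 and -1.10.

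Across all 18190 features, limma called 0 at an adjusted p under 0.05, while 2267 had an unadjusted p under 0.05 (567 higher and 1700 lower). After quantile normalization the unadjusted split was 1146 higher and 994 lower, and 18 features were called (11 higher and 7 lower). Centring called 14 (1 higher and 13 lower), array weights 55 and all 22 arrays with a dye term 522; in that fit the correlation between the arrays of a sample was 0.078, so they counted nearly as separate samples. With dye batch as a block 9 were called, all lower, among them S100a8, Timd4, Aqp1, Ccl24, Folr2 and Fbl (-0.48). The difference within batch 1 called 14 and that within batch 2 called 7, in 1 fit that pools the spread of both batches. A fit of the batch 2 samples alone called 0 (1641 of 16325 unadjusted), and the interaction with batch called 0 (1411 of 18157 unadjusted). Without Mdr2-KO tumour 2 the count was 34, without Mdr2-KO tumour 7 it was 4, without IkB-SR tumour 4 it was 12, and without the sample labelled IkB-SR replicate 8 it was 11, Nfkbia included (adjusted p = 0.0248 in limma). That sample stood out by its Nfkbia value, so this call of Nfkbia adds no separate support.

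The endothelial list fell as a group: all 23 measured genes were below 0, with a mean difference of -1.14 (camera adjusted p = 1.3e-17; adjusted p = 0.386 with an estimated correlation). Lyve1, a marker of liver sinusoids, differed by -2.02, the VEGF receptors Kdr by -1.67 and Flt1 by -0.63, the adhesion molecule Pecam1 by -1.64 and Aqp1 by -1.55. The probes of Flt1 differed from each other (-1.18 and -0.07). No member passed over all genes, and 21 were lower when adjusted over the list alone. The list differed by -1.23 within batch 1, -1.05 within batch 2 and -1.15 with the block. Its mean per tumour was below every Mdr2-KO tumour in 6 of 6 IkB-SR tumours (exact permutation p = 0.00476, adjusted 0.0508). Among the 7 tumours with low Eif2s3y the difference was -1.02, and -0.99 with Eif2s3y as a covariate.

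The macrophage and Kupffer cell list fell too, with 23 of 26 genes below 0 and a mean of -0.58 (camera adjusted p = 2.1e-07; adjusted p = 0.386 with an estimated correlation). Timd4, Cd5l and Vsig4 (-1.29), a complement receptor of Kupffer cells, led it. Clec4f, a Kupffer cell lectin, was at -1.19. Over all genes 0 members passed, and 13 were lower when adjusted over the list alone. The mean was -0.71 in batch 1, -0.51 in batch 2 and -0.62 with the block (exact permutation p = 0.0190, adjusted 0.122).

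The canonical NF-kB target list averaged -0.23, with 26 of 34 genes below 0 (camera adjusted p = 0.0414; adjusted p = 0.386 with an estimated correlation). Its leading members were the NF-kB inhibitor Tnfaip3 (-0.78) and the adhesion molecules Vcam1 (-0.75) and Icam1 (-0.79), while Nfkbia itself was higher. Over all genes 0 passed; adjusted over the list alone, 8 were lower and 1 higher. The mean was -0.23 in each batch and with the block, where the camera adjusted p was 0.057. The call was also lost after quantile normalization (-0.13, camera adjusted p = 0.0708) and with Eif2s3y as a covariate (-0.23, camera adjusted p = 0.206). Within batch 1, within batch 2 and among the 7 tumours with low Eif2s3y it was lost too (camera adjusted p = 0.104, 0.167 and 0.172). The control genes, not called by camera, lay about as low on the mean (-0.20, fry adjusted p = 0.0459). The NF-kB mean includes Nfkbia, the parent gene of the transgene, at 1.82. The medians were -0.26 for the NF-kB targets and -0.14 for the control genes. The S100 family averaged -0.46 with 10 of 11 genes below 0 (camera adjusted p = 0.00752; adjusted p = 0.386 with an estimated correlation). S100a8 (-2.09), S100a6 (-0.58) and S100a16 (-0.53) led it, and 5 members were lower when adjusted over the list alone. The median was -0.39. S100a8 was known from a paper on this model, so this list is not blind to published results. It was -0.55 in batch 1, -0.36 in batch 2 and -0.48 with the block, and -0.31 after quantile normalization, where the camera adjusted p was 0.064, and -0.41 with Eif2s3y as a covariate (camera adjusted p = 0.14). The S100 call was also lost within batch 2 (camera adjusted p = 0.0906) and among the 7 tumours with low Eif2s3y (-0.42, camera adjusted p = 0.0708).

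The antigen-presenting MHC class II genes averaged -0.71 with 7 of 7 below 0 (camera adjusted p = 0.0148; adjusted p = 0.688 with an estimated correlation), led by H2-DMb2 (-0.82), Cd74 (-0.72) and Ciita (-0.53); the list was -1.03 in batch 1, -0.54 in batch 2 and -0.82 with the block. Its call was lost with Eif2s3y as a covariate (-0.36, camera adjusted p = 0.433), among the 7 tumours with low Eif2s3y (-0.47, camera adjusted p = 0.152) and within batch 2 (camera adjusted p = 0.116). B and plasma cell genes averaged -0.54 with 6 of 7 below 0 (camera adjusted p = 0.0282; adjusted p = 0.386 with an estimated correlation), and 3 were lower when adjusted over the list alone. Pou2af1, a B cell coactivator, was at -1.35, Cd79b of the B cell receptor at -0.99 and the antibody joining chain Jchain at -1.06. The list was -0.45 in batch 1, -0.59 in batch 2 and -0.51 with the block, and its call was lost with Eif2s3y as a covariate (-0.51, camera adjusted p = 0.18), within batch 1 (0.108) and batch 2 (0.0906) and among the 7 tumours with low Eif2s3y (0.152). The MHC class II list had 0 members past the threshold either way.

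Hepatocyte genes averaged 0.24 with 17 of 26 above 0 (camera adjusted p = 3.5e-04; adjusted p = 0.544 with an estimated correlation). Beside Alb and Apoa2, Ttr, the thyroxine carrier, was at 0.97, and 1 member was higher when adjusted over the list alone. The list was 0.22 in batch 1, 0.16 in batch 2 and 0.19 with the block, and its camera call was lost after quantile normalization (mean 0.14, adjusted p = 0.36). Its mean per tumour gave an exact permutation p of 0.133 (adjusted 0.327). Cholesterol synthesis genes averaged 0.29 with 16 of 18 above 0 (camera adjusted p = 0.00752; adjusted p = 0.855 with an estimated correlation). Its enzymes Sqle (1.03), Msmo1 (0.59) and Mvk (0.24) led the list, which was 0.25 in batch 1, 0.59 in batch 2 and 0.40 with the block. It turned to -0.14 with Eif2s3y as a covariate (camera adjusted p = 0.891). Its call was also lost within batch 1 (camera adjusted p = 0.0806) and among the 7 tumours with low Eif2s3y (-0.02, camera adjusted p = 0.493). Drug-metabolising P450 genes averaged 0.13 (camera adjusted p = 0.019; adjusted p = 0.869 with an estimated correlation), but were 0.17 in batch 1, -0.28 in batch 2 and 0.00 with the block, where the call was lost (camera adjusted p = 0.14). With Eif2s3y as a covariate they were at 0.47 (camera adjusted p = 1.0e-04) and among the 7 tumours with low Eif2s3y at 0.40 (camera adjusted p = 2.3e-06). The fatty acid hydroxylases Cyp4a10 (-1.57) and Cyp4a14 (-1.27), below 0, and Cyp3a16 (0.73) led that list. Skin keratinocyte genes averaged 0.11 with a median of 0.00 (camera adjusted p = 0.0414; adjusted p = 0.389 with an estimated correlation), were 0.28 in batch 1, -0.06 in batch 2 and 0.13 with the block, and were led by the keratin Krt14 (0.62), Dmkn (0.47) and Krt1 (0.21). Their call was lost with the block (camera adjusted p = 0.0746) and with Eif2s3y as a covariate (camera adjusted p = 0.174). Adjusted over the list alone, 2 of these keratinocyte genes were higher, and 0 of the cholesterol and P450 genes passed.

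Of the 32 lists, the 10 above passed camera with the preset correlation, 0 passed with an estimated correlation, 6 with fry (endothelial, macrophage, NF-kB, S100, B and plasma cell and control genes) and 0 by exact permutation of the list means after adjustment. After quantile normalization 3 passed: endothelial, macrophage and MHC class II. Without Mdr2-KO tumour 7 or IkB-SR tumour 9, 6 passed. The other 22 lists had camera adjusted p-values from 0.144 to 0.901 and 0 members past the threshold over all genes. Their mean differences were -0.55 for neutrophil, -0.29 for extracellular matrix and stellate cell, -0.28 for cholangiocyte, -0.24 for interferon response, -0.22 for p53 target, -0.20 for immediate early, -0.20 for oncofetal, -0.20 for cell cycle and -0.14 for apoptosis genes. They were -0.10 for adipocyte, -0.10 for acute phase, -0.10 for T and NK cell, -0.07 for NRF2 target, -0.06 for bile acid, -0.04 for female-biased and -0.03 for endoplasmic reticulum stress genes. They were 0.18 for male-biased, 0.10 for pericentral, 0.05 for fatty acid oxidation, 0.02 for lipogenesis and 0.02 for periportal genes. The control genes averaged -0.20 (-0.21 after centring and -0.10 after quantile normalization), and lay below every Mdr2-KO tumour in 6 of 6 IkB-SR tumours (exact permutation p = 0.0143, adjusted 0.114); Actb was at -0.96.

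Mean and test differed in sign for the acute phase, bile acid, NRF2, endoplasmic reticulum stress and female-biased lists. Mean and median differed in sign for the fatty acid oxidation, lipogenesis, male-biased and T and NK cell lists. Quantile normalization turned the NRF2 (0.05), endoplasmic reticulum stress (0.06) and female-biased (0.04) means above 0. The p53 list passed with Eif2s3y as a covariate (-0.46, camera adjusted p = 0.017). Among the 7 tumours with low Eif2s3y the p53 (-0.405, camera adjusted p = 0.0441) and female-biased lists (0.21, camera adjusted p = 0.0441) passed. Over all tumours their camera adjusted p-values with an estimated correlation were 0.893 and 0.931. Cell cycle genes were at 0.23 in batch 1 and -0.75 in batch 2, past camera with the preset correlation in both; over all tumours the list had an estimated correlation of 0.617 between genes and an adjusted p = 0.911 with it. Male-biased genes were at -0.47 in batch 1 and 1.18 in batch 2 (camera adjusted p = 1.1e-05; adjusted p = 0.885 with an estimated correlation over all tumours). In batch 2 both IkB-SR tumours had high and both Mdr2-KO tumours low Eif2s3y; with Eif2s3y as a covariate the male-biased mean was -0.49, and without the sample labelled IkB-SR replicate 8 it was -0.05.

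**Figure D2:**
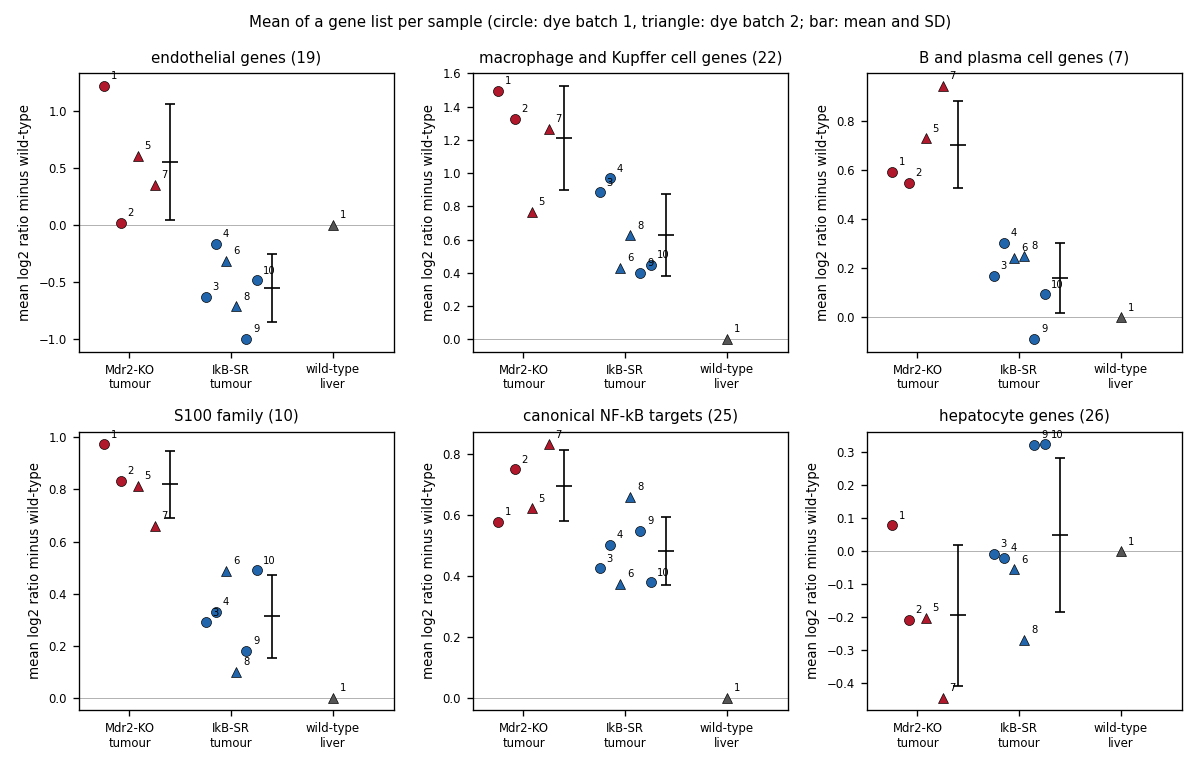
Mean log2 ratio of each gene list per sample minus the wild-type liver (vertical axis), by group, with circles for dye batch 1, triangles for dye batch 2 and bars for the mean and SD, for members measured in all samples. The endothelial, S100 and B and plasma cell means lie lower in 6 of 6 IkB-SR tumours than in every Mdr2-KO tumour.

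Against the wild-type liver, the genes that rose most in both tumour groups included several of lipid uptake and storage, while the lipogenesis list (mean 0.62, camera adjusted p = 0.259) and the adipocyte list (mean 0.61, median -0.06, camera adjusted p = 0.274) did not pass camera as groups. The lipogenesis list passed with the batch block (0.92, camera adjusted p = 0.0247), after quantile normalization (camera adjusted p = 0.0297) and with Eif2s3y as a covariate (1.02, camera adjusted p = 0.0385), but not with an estimated correlation (adjusted p = 0.631), and the adipocyte list passed fry (adjusted p = 0.0265). Cd36, a fatty acid transporter, rose by 3.46 (SE 0.33) in Mdr2-KO and 3.21 (SE 0.32) in IkB-SR tumours. Lpl, lipoprotein lipase, rose by 3.30 (SE 0.38) and 3.28 (SE 0.37), and Pparg, a regulator of fat storage, by 2.46 and 1.94. The peroxisomal fatty acid transporter Abcd2 rose by 3.91 and 3.60, the lipid-binding protein Osbpl3 by 3.55 and 3.37 and the lipid phosphatase Plpp2 by 2.39 and 2.29. Aldh2, which oxidises acetaldehyde, rose by 2.601 and 3.03, the membrane protein Rtn4 by 2.66 and 2.58, the necroptosis effector Mlkl by 1.88 and 2.03 and the galactokinase Galk1 by 1.53 and 1.59. Dpy19l3 was at -2.67 and -2.77, Arrdc2 at -2.19 and -1.95, the urinary protein gene Mup5 at -1.56 and -1.66 and the protease Capn8 at -1.18 and -1.19. All of these passed in both comparisons, with limma adjusted p-values from 0.00178 for Rtn4 to 0.0447 for Plpp2. All 4 Mdr2-KO tumours had low and the wild-type liver high Eif2s3y, so the Mdr2-KO comparison cannot separate tumour from sex.

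Mdr2-KO tumours had 43 called features against the wild-type liver (32 higher and 11 lower), and IkB-SR tumours 28 (19 higher and 9 lower), of 17419. The splits were 20 higher and 12 lower, and 15 and 13, after centring, and 12 and 15, and 13 and 11, after quantile normalization. Dye batch as a block gave 64 and 40. The Eif2s3y covariate gave 5 (5 higher and 0 lower) and 34 (23 higher and 11 lower). Within the wild-type liver's own dye batch limma called 0 in both, with 2215 and 1839 features at an unadjusted p under 0.05. For Mdr2-KO tumours the count was 17, 23 and 16 without Mdr2-KO tumours 1, 2 and 5 and 21 without IkB-SR tumour 10; for IkB-SR tumours it was 18 without IkB-SR tumour 10. The single liver lent the test no spread of its own, so the p-values cover the spread between tumours.

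Both comparisons shared 17 higher and 8 lower calls, where independent lists would share 0.0349 and 0.00568 and simulated groups without effect against the same liver 0.1 in each direction. Part of the excess may come from the shared liver. Neither baseline includes a liver that differs from both groups on its own, so neither limits how many calls it would share. Of the 25 shared features 19 were named, 15 higher and 4 lower, and 0 were called in opposite directions.

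Cell cycle genes rose in tumours as a group, with 33 of 36 above 0 and a mean of 0.81 (camera adjusted p = 3.2e-08; adjusted p = 0.474 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 1.56, the mitotic kinase Aurkb at 1.12 and the replication licensing factor Mcm2 at 1.23. Macrophage genes rose with 23 of 24 above 0 and a mean of 0.90 (camera adjusted p = 4.2e-07; adjusted p = 0.373 with an estimated correlation), with the lysosomal protein Laptm5 at 1.18, the adaptor Tyrobp at 1.56 and the lectin Lgals3 at 0.73. The NF-kB targets averaged 0.57, with 28 of 33 above 0 (camera adjusted p = 5.8e-04; adjusted p = 0.215 with an estimated correlation), including Icam1 at 1.18, the subunit Relb at 1.41 and the stress gene Gadd45b at 1.66. Immediate early and AP-1 genes averaged 0.76 (camera adjusted p = 2.1e-04; adjusted p = 0.229 with an estimated correlation). The transcription factors Egr2 (1.46, adjusted p = 0.0351) and Atf3 (1.91, adjusted p = 0.0431) rose on their own in limma, and Klf6 was at 1.75. NRF2 targets averaged 0.60 (camera adjusted p = 5.8e-04; adjusted p = 0.229 with an estimated correlation), with the antioxidant genes Srxn1 at 1.52 and Hmox1 at 1.32 and the epoxide hydrolase Ephx1 at 1.07. With dye batch as a block these lists had means of 0.85, 0.76, 0.57, 0.87 and 0.51, and each passed camera.

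Male-biased liver genes fell in tumours, with 9 of 9 below 0 and a mean of -2.23 (camera adjusted p = 1.3e-07; adjusted p = 0.215 with an estimated correlation). The organic anion transporter Slco1a1 was at -3.63, Selenbp2 at -2.57 and the nudix hydrolase Nudt7 at -2.31. On the mean of the list relative to the wild-type liver, the 3 tumours with high Eif2s3y lay at -2.17 to -1.03 and the 7 with low Eif2s3y at -2.57 to -1.50. With Eif2s3y as a covariate the mean was -1.36 and with the batch block -1.88. Bile acid genes averaged -0.68 (camera adjusted p = 0.00122; adjusted p = 0.474 with an estimated correlation), with Slc10a1, the bile acid uptake transporter, at -0.88, the synthesis enzyme Cyp27a1 at -0.55 and Slco1a1, also in this list. Pericentral genes averaged -0.69 (camera adjusted p = 0.00432; adjusted p = 0.474 with an estimated correlation), with the glutamate transporter Slc1a2 at -2.70, the aminotransferase Oat at -2.34 and Gulo, of vitamin C synthesis, at -1.31. The block gave -0.63 and -0.87 for these lists. Both camera calls were lost after quantile normalization (-0.52, adjusted p = 0.2, and -0.61, adjusted p = 0.0975).

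MHC class II genes averaged 0.79 (camera adjusted p = 0.0288; adjusted p = 0.474 with an estimated correlation), p53 targets 0.59 (camera adjusted p = 0.0288; adjusted p = 0.474 with an estimated correlation), extracellular matrix genes 0.37 (camera adjusted p = 0.0354; adjusted p = 0.509 with an estimated correlation) and interferon response genes 0.59 (camera adjusted p = 0.0456; adjusted p = 0.554 with an estimated correlation). Leading MHC class II genes were H2-DMa (1.53), H2-DMb2 (1.41) and the protease Ctss (1.81), and leading p53 targets were the kinase Plk2 (1.27), Btg2 (1.40) and the growth factor Gdf15 (1.63). Leading matrix genes were Thy1 (0.40), the fibrillin Fbn1 (0.78) and Sparc (1.20), and leading interferon genes were the proteasome subunit Psmb9 (1.20), the peptide transporter Tap1 (1.36) and Usp18 (1.77). With dye batch as a block the MHC class II (0.36, adjusted p = 0.374), extracellular matrix (0.38, adjusted p = 0.0849) and interferon lists (0.42, adjusted p = 0.326) no longer passed, and after quantile normalization the p53 (adjusted p = 0.0507) and matrix lists (adjusted p = 0.428) did not. With Eif2s3y as a covariate the MHC class II, matrix and interferon lists were lost too (camera adjusted p = 0.3535, 0.433 and 0.242). The matrix list was also lost without the sample labelled IkB-SR replicate 8 (camera adjusted p = 0.0627). In all 12 lists were called, 0 with an estimated correlation and 5 with fry (male-biased, immediate early, NRF2, NF-kB and adipocyte genes). Adjusted over the list alone, 5 macrophage, 5 NRF2, 4 immediate early and 4 MHC class II genes were higher, 4 male-biased, 1 bile acid and 1 pericentral gene were lower, and 0 passed in the cell cycle, NF-kB, p53, extracellular matrix and interferon lists. Over all genes 2 immediate early genes passed, and 0 in the other 11. Of the lists below, lipogenesis held 2 called genes (Cd36 and Pparg), adipocyte 2 (Lpl and Pparg) and endoplasmic reticulum stress 1 (Atf3).

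The remaining 20 lists had camera adjusted p-values from 0.0859 to 0.769 against the wild-type liver. Their means were 0.78 for neutrophil, 0.75 for oncofetal, 0.62 for lipogenesis, 0.61 for adipocyte, 0.58 for S100, 0.55 for female-biased, 0.43 for B and plasma cell, 0.35 for apoptosis, 0.26 for fatty acid oxidation, 0.22 for cholangiocyte and 0.22 for control genes. They were 0.04 for P450, 0.02 for endoplasmic reticulum stress, 0.02 for skin keratinocyte, -0.00 for endothelial, -0.01 for acute phase, -0.05 for T and NK cell, -0.07 for hepatocyte, -0.16 for cholesterol and -0.20 for periportal genes. With dye batch as a block 4 of them passed camera: hepatocyte (-0.24), P450 (-0.43) and periportal genes (-0.45) below 0 and lipogenesis genes (0.92) above 0. Without the block their adjusted p-values with an estimated correlation were 0.633, 0.691, 0.474 and 0.631. The cholesterol mean turned to 0.21 with the block. The P450, endoplasmic reticulum stress and keratinocyte means turned below 0 after centring (-0.03, -0.05 and -0.06), and the acute phase, hepatocyte and endothelial means above 0 after quantile normalization (0.04, 0.07 and 0.02). The test had the opposite sign to the mean for the P450, fatty acid oxidation, cholangiocyte, endoplasmic reticulum stress and keratinocyte lists, and the median to the mean for the P450, cholangiocyte, endoplasmic reticulum stress, keratinocyte, T and NK cell and adipocyte lists.

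**Figure D3:**
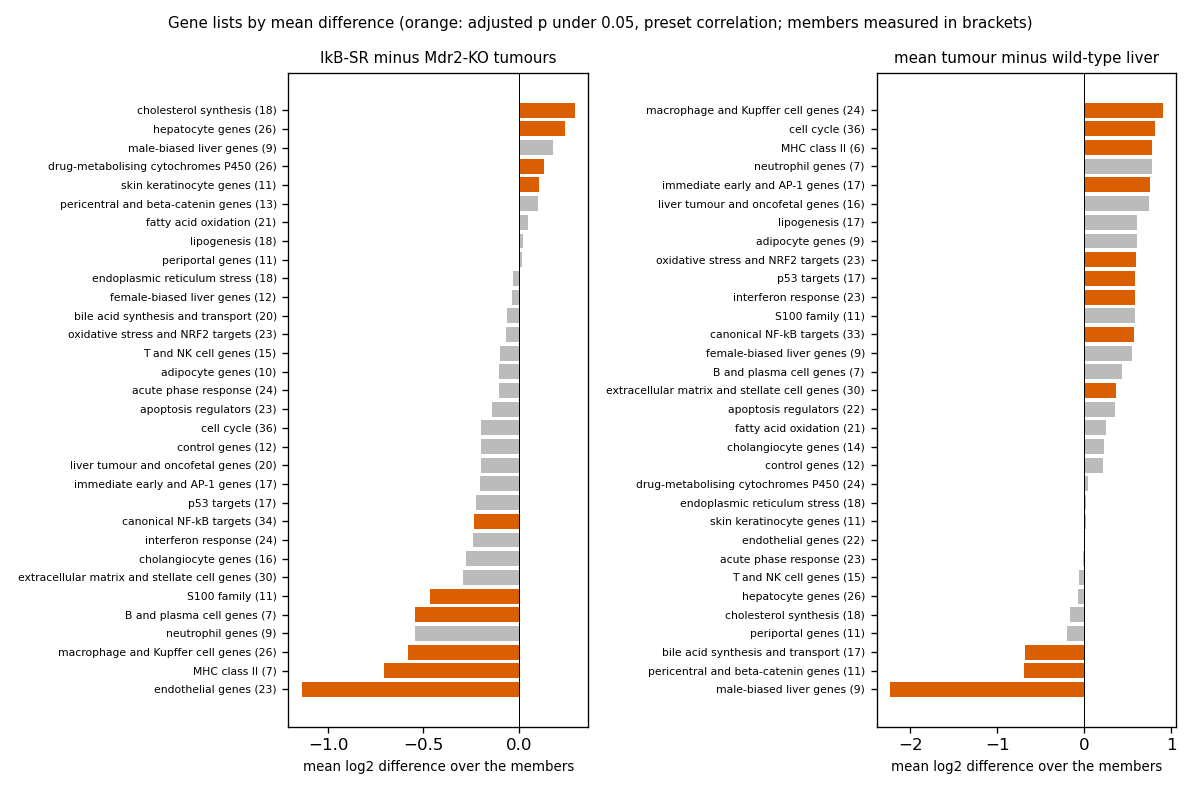
Mean log2 difference (horizontal bars, from 0) of the 32 tested gene lists for IkB-SR against Mdr2-KO tumours and for tumours against the wild-type liver, in orange where the camera adjusted p with the preset correlation is under 0.05. The longest bars are the endothelial list at -1.14 in the former and the male-biased list at -2.23 in the latter.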

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

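Of the tests in this part, the regroupings of the samples and the position of the sample labelled IkB-SR replicate 8 between the groups were set before their results were seen, and all others were chosen only after the result was seen. The limits for dye batch, sex and male-biased genes were made stricter after the values were seen.

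Among 258 groups of 4 to 6 tumours examined, 8 held 1 tumour far from the others by Dixon's test, where chance gives about 1 in 20, or 12.9. The sample labelled IkB-SR replicate 8 lay far above the other IkB-SR tumours in Cxcl9 (2.55) and Icam1 (1.45). Mdr2-KO tumour 5 lay low in Cd74 (1.27) and high in the lipogenesis list (mean 2.17). IkB-SR tumour 6 lay high in the lipogenesis list (mean 2.85) and low in the female-biased list (mean 1.42). IkB-SR tumour 9 lay low in Osbpl3 (-0.94) and IkB-SR tumour 4 in Capn8 (0.12).

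The first pattern is the lower endothelial and macrophage genes in IkB-SR tumours. Dye batch is excluded as the whole cause. Within dye batch 2, where each difference was smaller, the endothelial list was at -1.05 and the macrophage list at -0.51. Exact permutation within the batches gave p-values of 0.0111 and 0.0222. In dye batch 2 both IkB-SR tumours had high and both Mdr2-KO tumours low Eif2s3y, so its values cannot separate the repressor from sex. A lower share of every cell type other than hepatocytes would lower the matrix and stellate list alike, if its genes come from those cells alone. Whether they do was not tested. The endothelial list fell further than the matrix list by 0.83 (difference -0.8328, exact permutation p = 0.00476, the smallest possible). This argues against an equal fall of these cells as the whole cause there. The macrophage list differed from the matrix list by -0.32 (exact permutation p = 0.0762), which leaves an equal fall open. High Eif2s3y occurred in tumours of the IkB-SR group alone, and with it as a covariate the lists were at -0.99 and -0.39, past camera with the preset correlation (adjusted p = 0.386 for both with an estimated correlation and no covariate); sex stays open because the means of the 7 tumours with low Eif2s3y differed by -1.02 and -0.44 with exact permutation p-values of 0.0571 and 0.114, and the repressor itself, tumour stage and the dissected tissue stay open.

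The second pattern is the sample labelled IkB-SR replicate 8, with Nfkbia at the Mdr2-KO level. On an axis from the Mdr2-KO mean (0) to the IkB-SR mean (1) over features chosen without this sample, it lay at 0.71. Mdr2-KO tumours lay at -0.01 to 0.52 and other IkB-SR tumours at 0.54 to 1.1. That position goes against a Mdr2-KO tumour under a wrong label but does not exclude it. This sample had high Eif2s3y (1.64) and no Mdr2-KO tumour did, so the axis cannot separate the label from sex. Little active transgene in this tumour is a candidate explanation: its NF-kB target list lay 0.1123 above the highest other IkB-SR tumour (0.66 over the wild-type liver, against 0.374 to 0.548 in the others and 0.578 to 0.832 in Mdr2-KO tumours). Icam1 is a member of that list and was seen first. S100a8 (-1.15) lay on the IkB-SR side in this sample, so not all of its values went with the Mdr2-KO group.

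The third pattern is a stretch of neighbouring genes around Vegfa, the endothelial growth factor, that was high in 3 of 4 Mdr2-KO tumours. Vegfa was at 1.42, 1.34 and 1.61 in Mdr2-KO tumours 1, 5 and 7, -0.15 in Mdr2-KO tumour 2 and -1.10 to -0.50 in IkB-SR tumours (difference -1.96, adjusted p = 0.0753 in limma), and the highest median of 9 neighbouring genes with Vegfa, each gene taken relative to its median over the 10 tumours, was 1.38, 1.98 and 1.71 in those 3. A chance order of genes is excluded, since 100 shuffles gave at most 0.9467 in any tumour. Genes next to each other in the order of the deposited spots gave at most 0.7076. Whether that order follows the layout of the array is not known here, so a position effect on the array stays open. The window found in Mdr2-KO tumour 5 was tried first and recurred in tumour 7 (1.45) but not in tumour 1 (-0.02); the window found in tumour 1 was then set and gave 1.98 in tumour 5 and 1.245 in tumour 7, against -0.33 to 0.12 in the 7 other tumours. Gain of this stretch in the tumour DNA is a candidate explanation that stays open, because DNA was not analysed here and regulation shared by neighbours would give the same values; runs of neighbours above all shuffles were not confined to this stretch: counting it, there were 5 in Mdr2-KO tumour 1 (the highest, Tepsin to Hgs, at 1.45), 4 in Mdr2-KO tumour 7 and 1 each in Mdr2-KO tumours 2 and 5 and IkB-SR tumours 3 and 4.

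Of 100 splits of the 10 tumours into 4 and 6, 1, the real one, gave as many features at an unadjusted p under 0.05 (2267, highest other 2241). That share lies under 0.05, but the margin was small and a split left out of the 100 gave more, so chance is not excluded. By features called in limma the real split did not stand out, with 0 called, while 4 of the other splits called 1 to 3. The highest other split held 4 tumours of dye batch 1. The split along dye batch itself was not among the 100 and gave more, with 2719 unadjusted and 25 called by limma against 0 in the real one, which points to a batch structure of the samples; with the batch as a block 9 were called, within batches 1 and 2 14 and 7 with the spread pooled over both, and with the batch 2 samples fitted alone limma called 0 (1641 unadjusted). For gene lists 10 of 100 splits gave as many (10, highest other 14), so chance is not excluded for the count of lists. The other splits gave a median of 6 lists past camera with the preset correlation, against 0 false lists in the simulated data, where genes were independent. For the endothelial mean 1 of 210 splits was as large (-1.10, highest other 1.03 in size). A first version of these counts, on the tumours alone and 15023 features, gave 2 of 100 for 1880 unadjusted features (highest other 1952), 1 of 100 for 19 called (highest other 5) and 30 of 100 for 8 lists (highest other 12). Set alone against the 10 others, 2 of 11 samples gave as many called features as the wild-type liver (35; Mdr2-KO tumour 1 gave 69); 11 samples are too few for a share under 0.05.

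Male-biased genes stayed below the wild-type liver in the 3 tumours with high Eif2s3y (nearest mean -1.03), and sex cannot be told apart because 1 wild-type liver was measured.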

How the results depend on the processing

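The added alternatives (dye batch, Eif2s3y, the threshold of 0.10, exact permutation of lists and features in all 10 tumours) were chosen only after the data were seen; the others were planned. The planned Xist covariate was not run, because Xist is not named on the array. No paired analysis was possible because the 2 tumour groups share no replicate number and the wild-type liver shares 1 number with 1 tumour. Spot intensities were not analysed here, so signal over background sets no limit that could be given.

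For IkB-SR against Mdr2-KO tumours the count of 0 became 14 with centring, 18 with quantile normalization, 2 with the Cy3 and 1 with the Cy5 arrays alone, 522 with all 22 arrays (within-sample correlation 0.078, so arrays counted nearly as separate samples, here and below), 8 with features on all 22 arrays, 18 without features of smaller range, 1 with single probes, 55 with array weights, 19 with the tumours and features in all 10, 9 with the batch block, 21 among the 7 tumours with low Eif2s3y, 14 and 7 within batches 1 and 2 (spread pooled over both), and 74 at 0.10. It stayed 0 in limma with no filter, robust eBayes, the tumours alone, the Eif2s3y covariate alone or with batch, the fold threshold, and batch 2 fitted alone (1641 unadjusted). Leaving out 1 tumour gave 0 to 34, the highest without Mdr2-KO tumour 2. The cause was not tested.

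For Mdr2-KO tumours against wild-type liver the count of 43 became 27 with quantile normalization, 12 with Cy3, 24 with Cy5, 576 with all 22 arrays, 66 with no filter, 68 with array weights, 5 with Eif2s3y, 7 with Eif2s3y and batch, and 0 within the batch of the wild-type liver, where fewer samples were tested (2215 unadjusted in limma). For IkB-SR tumours the count of 28 became 12 with Cy3, 373 with all 22 arrays, 59 with Eif2s3y and batch and 0 within that batch (1839 unadjusted in limma). Leaving out 1 tumour gave 16 (without Mdr2-KO tumour 5) to 47, and 18 (without IkB-SR tumour 10) to 33. The cause was not tested.

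The 10 lists between the tumour groups became 0 with an estimated correlation, 6 with fry, 0 by exact permutation, 3 with quantile normalization, 6 with Cy5, 5 with Eif2s3y, 6 within batch 2 and 6 among the 7 tumours, and 6 (without Mdr2-KO tumour 7 or IkB-SR tumour 9) to 11 with 1 tumour left out. Some counts held lists outside the 10: p53 with Eif2s3y, cell cycle and male-biased within batch 2, and p53 and female-biased among the 7 tumours. The 12 lists against wild-type liver became 0 with an estimated correlation and 5 with fry. With 1 tumour left out the Nfkbia difference ranged from 1.59 to 2.21, the highest without the sample labelled IkB-SR replicate 8, and its exact p was 0.0833 without Mdr2-KO tumour 2, 5 or 7. The cause was not tested.

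The Abcb4 difference of -0.13 turned to 0.0528 with quantile normalization and ranged from -0.3613 to 0.04467 with 1 tumour left out, the highest without Mdr2-KO tumour 1, and Sqle to -0.19 with Eif2s3y; the cause was not tested. Over 51 named genes between the tumour groups, 1148 of 1289 values kept direction and side of the threshold, 132 passed it newly, 6 lost it and 3 reversed. Over 49 against wild-type liver it was 1082 of 1168, with 19 newly past it, 67 no longer past it and 0 reversed. Between the tumour groups, Abcb4 and Eif2s3y were judged by the exact permutation p and the other genes by the limma adjusted p. All 6 losses there were of Eif2s3y with 1 IkB-SR tumour left out, since no feature passed limma in the main fit.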

Other observations

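The genes and tests in this part were chosen only after the values were seen.

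Igf2, the fetal growth factor, was high in Mdr2-KO tumour 2 (4.58) and IkB-SR tumours 4 (4.64) and 10 (2.69), while the other tumours lay between -2.83 and 0.16 and the wild-type liver at -0.96. H19, the imprinted RNA gene beside it, was at 3.80, 2.59 and 1.85 in these 3, and also high in Mdr2-KO tumour 1 (2.25) and the sample labelled IkB-SR replicate 8 (2.88). It was lowest in IkB-SR tumour 6 (-3.74), with the wild-type liver at -2.84. Both groups held tumours with high and low values.

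IkB-SR tumour 6 had the highest Fasn, fatty acid synthase, at 4.30, where the other tumours lay between -0.16 and 2.04. Its cholesterol synthesis list lay 0.90 above the wild-type liver. That list was lowest in Mdr2-KO tumour 1 (-0.96) and IkB-SR tumour 3 (-1.04), with Sqle at -3.22 and -2.99.

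Over the 7 tumours with lower Igf2, Igf2 and H19 had Pearson's r = 0.8139 (exact permutation p = 0.0357, adjusted over both coefficients 0.0714) and Spearman's rho = 0.643 (exact permutation p = 0.139). Without the 2 tumours farthest from the median Igf2 (Mdr2-KO tumour 5 and IkB-SR tumour 6) r was 0.524 (exact permutation p = 0.35). A correlation over all 10 was set aside because the 3 tumours with high Igf2 form a cluster. Whether the neighbours vary together stays open at this number of tumours.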
